A study of Oryza sativa Japonica Group with 33 samples.

How the data were processed

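Total RNA of rice embryos (cultivar Nipponbare) was extracted with a PicoPure kit, mixed with a one-colour spike mix, labelled with Cy3 by a Quick Amp kit and hybridised to Agilent 44K arrays, per the labels. There were 33 arrays in 11 groups of 3: whole embryos at 2, 3 and 4 days after pollination (DAP), apical, basal, dorsal and ventral parts of 3-DAP embryos, and shoot, root, scutellum and epiblast of 7-DAP embryos. The label of the last group says epiblast, and the series text adds the coleorhiza. How many embryos went into a sample, whether the replicates are separate embryos, and whether equal replicate numbers mark samples from the same embryos are not given in the sources used here.

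Per the file headers, the intensity values (gProcessedSignal) were made by Agilent Feature Extraction 10.5.1.1, which subtracted the background and removed spatial trends within each array, and replaced low signals by a surrogate. The deposited table holds log2 values of the same signals with no further scaling or centring, since they differ from log2(gProcessedSignal) by at most 2.4e-06, and its column medians ran from 5.12 to 7.02. Its values were used as an alternative. Each array had 45151 spots, 43734 of them not controls, for 42477 probes. Of these 41889 name a locus of the Rice Annotation Project (29689 loci, 7796 with several probes) and 588 do not (510 of them for microRNA precursors and 51 controls of the design). The loci were looked up in the reference table that pairs locus tags with symbols, and 0 matched, so genes are named by locus and by the description in the files. Gene symbols are the commonly used names of these loci, fixed beforehand. CRL1, WOX3B, NAL2 and NAL3 had no probe.

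Control spots were left out, spots marked as outliers by the scanner software (14 to 98 per array) were set to missing, and spots of a probe were averaged. Signals were put on the log2 scale, and each array's 75th percentile was subtracted. A locus was represented by its probe with the highest mean signal over the 33 arrays. Probes of a locus were called in opposite directions at 7, 21 and 35 of 5084 loci with several tested probes in 3 against 2, 4 against 3 and 4 against 2 DAP, at 6 and 0 of 5179 in the comparisons of parts, and at 3, 9, 10 and 1 of 5863 in shoot, root, scutellum and epiblast. A gene was kept in a set when it was well above background on all 3 arrays of at least 1 group, which left 17196, 17431 and 20354 genes. Of these 13797, 14103 and 16297 were well above background on every array of the set.

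Of the non-control spots of an array 51.2 to 72.8 percent were well above background, 15.3 to 35.2 percent had a surrogate signal and 0 were saturated. Replicates correlated at 0.930 to 0.992. The test was also run on simulated arrays drawn with each gene's own mean and spread, with changes put into 200 genes per comparison. It recovered 69.7 to 90.9, 44.8 to 70.1 and 23.9 to 34.3 percent of genes changed 4-fold, 2-fold and 1.5-fold, and 2.7 to 8.1 percent of its calls were false. Slide effects and deviations shared by replicate numbers were not simulated, so the data may hold more false calls.

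Each set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with group means and no block. Contrasts were 3 against 2, 4 against 3 and 4 against 2 DAP, apical against basal, dorsal against ventral, and each organ against the mean of the 3 other organs. Tests were two-sided with Benjamini-Hochberg adjustment over the genes of a set and a threshold of 0.05. A gene that was well above background on no array of one side, or of 1 or more of the other organs, got a lower bound of its fold. This is the mean of the brighter side set against, per array of the dim group, the higher of the gene's own signal and the lowest signal well above background. No fold is given where this is under 1 or where both sides are dim. Scripts used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

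Of 25 gene lists, 23 were built from loci or words of the descriptions for embryo biology, and 2, the endosperm markers and the seed storage protein genes, as markers of RNA from the endosperm. Lists with at least 5 tested members were tested with cameraPR of limma (preset correlation 0.01) and adjusted over the lists of a comparison. The estimated correlation was taken between the members of each list after the fit. This gave 209 tests, of which 80 passed, 7 with an estimated correlation and 130 with the rotation test fry. A list's median is of fitted log2 changes, and "with bounds" of the same changes with dim members at their bound and members without a fold at 0. Of 5 HD-Zip III genes on the arrays 4 were kept, too few for a test. Members were also counted after adjustment over the list alone. For the parts of 3-DAP embryos, the 200 genes with the highest statistic toward each part were tested as sets in the 4 organ contrasts, with adjustment over the 16 tests, and the relation of the 2 axes is the correlation of their changes over genes.

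The comparisons, the tests, the lists, the alternatives not named as added later and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 6 genes changed most upward and the 6 changed most downward among called genes that were well above background on all arrays, whose groups did not overlap and that had a description. It adds up to 3 called members of each list, those changed most, and always OSH1, QHB, SCR1, DL, ROC1, VP1, LEC1A and GA3ox2. The report names a part of these genes, chosen for what they do. All are in the tables.

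The 33 arrays lay on 9 slides, scanned on 3 days with 1 scanner. No slide held all groups of a set, and 1 held only 4-DAP replicate 3, alone on its scan day. Slide and group thus overlap in part, and comparisons were repeated with the slide as a fixed block, as a random block, and within the slides that held both groups. Other alternatives were normexp background correction (offset 50) of the mean signal, quantile normalization, the deposited table, a strict filter and none, array weights, every probe as its own feature, all arrays in 1 fit, only the compared groups in the fit, a replicate block, a 2-fold threshold, and the removal of each array. Replicate numbers were used as a block only there. Deviations of equal replicate numbers from their group means correlated between 0.214 and 0.676 in the organs, between 0.316 and 0.609 for apical and basal parts, and between 0.201 and 0.458 for dorsal and ventral parts, so the replicate-blocked result is given where it changes a call. Added after the data were seen were normexp followed by quantile normalization, the removal of arrays at 1 position of the slide, of libraries high in endosperm genes and of replicate 3 of 3 parts, cameraPR on z-scores, and lists cleaned of members whose description did not match. Spike probes, and probes without a locus, were not used in the comparisons.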

Results

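Transcript levels were measured in embryos of the rice cultivar Nipponbare on 33 Agilent arrays, 1 labelled RNA sample per array, in 11 groups of 3 arrays. The first set held whole embryos collected at 2, 3 and 4 days after pollination (DAP). The second set held 3-DAP embryos cut by laser microdissection into an apical and a basal part, or into a dorsal and a ventral part. The third set held 4 organs of 7-DAP embryos: the shoot, the root (radicle), the scutellum, which is the absorbing organ next to the endosperm, and the epiblast, a flap of tissue collected together with the coleorhiza, the sheath of the radicle. The 75th percentile of the signal ran from 262.9 to 902.6 intensity units. Correlations between replicates were lowest in the apical part, at 0.930, and 3 arrays per group limit the precision.

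Changes are differences of log2 levels with the standard error of the fit (SE, n = 3 arrays per group), and a gene or list is said to have risen, fallen or changed when limma's two-sided test gave an adjusted p under 0.05. The labels do not say whether the replicates are separate embryos, so the p-values measure the spread between arrays. Where a gene was well above background on no array of one side, or of 1 or more of the other organs, its change is given only as a bound, "at least N-fold". This is taken against the lowest signal that counts as well above background. Counts of list members are over all genes tested, and counts adjusted over the list alone follow where they differ from these. Each set had its own fit, with 17196, 17431 and 20354 genes tested.

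The comparison of 3 DAP with 2 DAP follows whole embryos through the globular stages, before organs are visible. YABBY genes encode transcription factors of leaves and other lateral organs. Of the 6 tested 3 rose and 0 fell, YAB4 (Os02g0643200) by 6.06 ± 0.12, YAB3 (Os10g0508300) by 3.14 ± 0.17 and YAB5 (Os04g0536300) by 2.58 ± 0.12. YAB4 was well above background on 1 of 3 arrays at 2 DAP. OSH15 (Os07g0129700) and OSH71 (Os05g0129700), KNOX homeobox genes active in and around the shoot meristem, rose by 3.96 ± 0.17 and 2.30 ± 0.24.

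Genes of root patterning and of the WOX family, homeobox genes of stem cell niches and early embryo domains, moved in both directions from 2 to 3 DAP. QHB (Os01g0854500), the WOX gene of the quiescent centre of the root, rose by 2.12 ± 0.21, and WOX11 (Os07g0684900), a gene of crown root formation, rose at least 2.7-fold. WOX2 (Os01g0840300) fell by 1.08 ± 0.11. PIN1d (Os12g0133800), which encodes an auxin efflux carrier, rose by 2.09 ± 0.26, while the related PIN1a (Os06g0232300) fell by 1.13 ± 0.17. As lists, WOX genes (3 of 7 rose, 1 fell, adjusted p = 0.11) and root patterning genes (4 of 11 rose, 2 fell, adjusted p = 0.81) did not pass. Auxin transport genes (3 of 5 rose, 2 fell, adjusted p = 0.57) did not pass either. Nor did the KNOX and shoot meristem genes (3 of 10 rose, 4 fell, and 4 and 5 adjusted over the list alone, adjusted p = 0.70), whose median of -0.32 and mean of 0.61 differ in sign.

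Among the largest single changes, the NAC transcription factor gene OsNAC5 (Os11g0184900) rose by 3.93 ± 0.17 and a gene for an ERECTA-like receptor kinase (Os06g0130100) by 3.45 ± 0.11. A gene for a Dof zinc finger transcription factor (Os02g0707200) fell by 4.59 ± 0.19.

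Of 288 ribosomal protein genes, 142 rose and 2 fell (163 and 2 adjusted over the list alone, median 0.28, adjusted p = 1.1e-10, and 0.60 with an estimated correlation). Lipid transfer protein genes, many of which are active in outer cell layers, fell as a list, with 11 of 22 lower and 6 higher (14 and 6 adjusted over the list alone, median -0.99, adjusted p = 1.0e-07, and 0.62 with an estimated correlation). Os12g0115300 and Os11g0116000 fell by 3.56 ± 0.22 and 3.13 ± 0.12, while the member Os01g0691100 rose at least 23.1-fold. Of the 7 HD-Zip IV genes, transcription factor genes of the epidermis, 3 fell and 0 rose, among them ROC4 (Os04g0569100) by 1.48 ± 0.19 (list median -0.40, adjusted p = 0.022, 0.62 with an estimated correlation and 0.058 without the libraries high in endosperm genes). YABBY genes rose as a list (median 1.57, or 1.29 with bounds, adjusted p = 3.5e-19, and 0.62 with an estimated correlation). With the slide as a block, and within the slide that held arrays of both stages, 3-DAP replicate 1 is the only array compared with 2 DAP. The medians there were 0.30 for ribosomal protein genes, -0.99 for lipid transfer protein genes, -0.43 for HD-Zip IV genes and 1.51 for YABBY genes.

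The test called 4923 of 17196 genes, 2746 higher and 2177 lower at 3 DAP, and 1574 of them changed at least 2-fold (706 higher, 868 lower). With 3-DAP replicate 1 alone it called 4558 (slide as a block) and 4097 (within the shared slide, 1991 higher and 2106 lower), assuming that this array varies like the others. With the unscaled deposited values it called 1500 genes, 560 higher and 940 lower, with the median of all genes moved by -0.11, and with normexp background correction 121 genes (59 higher, 62 lower).

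The comparison of 4 DAP with 3 DAP covers the day on which shoot and radicle become visible. A metallothionein gene (Os05g0111300) and a thionin gene (Os02g0629800), for a metal-binding and a defence peptide, each rose by 8.18 ± 0.36, and an aquaporin gene (Os04g0559700) rose by 6.60 ± 0.18. Of 15 oleosin and LEA genes, for proteins of oil bodies and of desiccation tolerance, 10 rose and 1 fell (median 2.34, or 1.90 with bounds, adjusted p = 5.5e-06, and 0.15 with an estimated correlation). The oleosin gene Os04g0546500 rose by 3.81 ± 0.16 and ABI5 (Os01g0859300), a bZIP regulator of abscisic acid response in seeds, by 2.91 ± 0.27.

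From 3 to 4 DAP 10 of 11 root patterning genes fell and 0 rose (median -1.32, adjusted p = 9.7e-05, and 0.29 with an estimated correlation). QHB fell by 2.08 ± 0.21 and BBM3 (Os01g0899800), an AP2 gene of the BABY BOOM group, by 2.01 ± 0.13. SCR1 (Os11g0124300), a GRAS gene of the root endodermis, fell by 1.95 ± 0.30 with 2 of 3 arrays at 4 DAP well above background. All 5 auxin transport genes tested fell (median -0.82, adjusted p = 0.032, and 0.29 with an estimated correlation), PIN1a by 1.87 ± 0.17. WOX2 fell by 2.27 ± 0.11, and WOX6 (Os03g0325600) rose at least 12.3-fold, in a WOX list with 2 of 7 higher and 3 lower (adjusted p = 0.53). YABBY genes, 4 of 6 higher and 1 lower, did not pass (median 0.71, adjusted p = 0.097), nor did KNOX and shoot meristem genes (2 of 10 higher, 2 lower, adjusted p = 0.88) and HD-Zip IV genes (1 of 7 higher, 4 lower, adjusted p = 0.29).

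All 4 alpha-amylase genes tested, for starch-degrading enzymes, rose, the isozyme 3E gene (Os08g0473600) by 7.54 ± 0.48 with 1 of 3 arrays at 3 DAP well above background. They were too few for a list test. Photosynthesis genes rose, 14 of 26 higher and 0 lower (median 0.84, adjusted p = 4.8e-05, and 0.22 with an estimated correlation), among them a chlorophyll a-b binding protein gene (Os01g0720500) by 5.50 ± 0.32. Of 6 gibberellin metabolism genes 4 rose and 0 fell (median 1.48, adjusted p = 0.034, and 0.22 with an estimated correlation), with GA20ox1 (Os03g0856700), for an enzyme late in gibberellin synthesis, higher by 2.15 ± 0.22. Of 22 lipid transfer protein genes 9 rose and 6 fell (median 0.19, mean 1.02, adjusted p = 0.034, and 0.45 with an estimated correlation), a call that ended without the libraries high in endosperm genes (adjusted p = 0.13).

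Of 288 ribosomal protein genes 233 fell and 16 rose at 4 DAP (236 and 19 adjusted over the list alone, median -0.61, adjusted p = 2.2e-20, and 0.22 with an estimated correlation). Of 22 DNA replication genes 16 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.66, adjusted p = 0.011, and 0.29 with an estimated correlation), such as the origin recognition complex gene Os06g0187000, which fell by 1.07 ± 0.12. Of 91 heat shock protein genes 40 fell and 7 rose (40 and 8 adjusted over the list alone, median -0.35, adjusted p = 0.032, and 0.34 with an estimated correlation). Of 47 histone genes 26 fell and 2 rose (30 and 3 adjusted over the list alone, median -0.48, adjusted p = 0.013, and 0.45 with an estimated correlation), though with normexp correction the test of histone genes turned upward (adjusted p = 0.59).

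Seed storage protein genes rose too, 14 of 21 higher and 1 lower at 4 DAP (median 3.23, or 1.97 with bounds, adjusted p = 0.0027, and 0.29 with an estimated correlation). So did the endosperm markers, genes of starch and storage protein synthesis in endosperm, 3 of 14 higher and 0 lower (median 1.75, adjusted p = 0.028, and 0.43 with an estimated correlation). The glutelin gene GluA1 (Os01g0762500), dim at 3 DAP, rose to -1.97, 3.18 and -0.64 in replicates 1, 2 and 3. Both lists stood highest in replicate 2 of 4 DAP: the median endosperm marker was above its 3-DAP mean by 0.58, 3.08 and 1.18 in replicates 1, 2 and 3. The 21 storage genes tested were higher in replicate 2 than in replicates 1 and 3 by a median of 3.98, and replicates 1 and 3 were above 3 DAP by a median of 1.87.

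The test called 8234 of 17196 genes, 2812 higher and 5422 lower at 4 DAP, and 2814 of them changed at least 2-fold (1379 higher, 1435 lower). With the slide as a block it called 8071 and within the slide that held both stages 7808. Both gave medians of -1.30 for root patterning genes, -0.58 for auxin transport genes, 2.23 for oleosin and LEA genes, 1.32 for gibberellin metabolism genes, 0.61 for photosynthesis genes and 0.33 for lipid transfer protein genes. The medians were -0.61 for ribosomal protein genes, -0.54 for DNA replication genes, -0.36 for heat shock protein genes and -0.34 for histone genes. Endosperm markers stood at 2.09 (adjusted p = 0.053 within the slide) and seed storage protein genes at 3.91. The slide block ended the calls of gibberellin metabolism genes (adjusted p = 0.058) and auxin transport genes (0.067). With the unscaled deposited values 2894 genes were higher and 618 lower, with the median of all genes moved by 0.49. With normexp correction 1321 genes passed. This ended the calls of gibberellin metabolism genes (adjusted p = 0.56), ribosomal protein genes (0.91), photosynthesis genes (0.096), auxin transport and DNA replication genes (0.070 each) and heat shock protein genes (0.11).

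From 2 to 4 DAP YABBY genes rose, 5 of 6 higher and 0 lower (median 3.73, or 2.12 with bounds, adjusted p = 6.2e-11, and 0.28 with an estimated correlation), YAB4 by 6.79 ± 0.12 (1 of 3 arrays at 2 DAP well above background) and YAB3 by 3.83 ± 0.17. OSH15 rose by 4.47 ± 0.17 and OSH71 by 3.98 ± 0.24, in a KNOX and shoot meristem list that did not pass (3 of 10 higher, 6 lower, median -0.49, adjusted p = 0.60). WOX6 rose at least 16-fold and WOX11 at least 10.6-fold. WOX2 fell by 3.36 ± 0.11, PIN1a by 3.00 ± 0.17 and BBM3 by 2.95 ± 0.13. QHB, which had risen and then fallen, differed by 0.03 ± 0.21 (adjusted p = 0.90).

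Genes for a type 3 metallothionein (Os01g0200700), a tonoplast aquaporin (Os03g0146100) and ACC oxidase (Os09g0451000), the last enzyme of ethylene synthesis, rose by 7.83 ± 0.44, 6.65 ± 0.61 and 6.46 ± 0.15 over the 2 days. The HSP70 chaperone gene Os11g0187600 fell at least 112.9-fold. Oleosin and LEA genes rose (10 of 15 higher, 1 lower, and 11 and 1 adjusted over the list alone, median 2.63, or 2.33 with bounds, adjusted p = 0.00018, and 0.20 with an estimated correlation). So did seed storage protein genes (14 of 21 higher, 0 lower, and 15 and 0 adjusted over the list alone, median 4.12, or 2.27 with bounds, adjusted p = 0.013, and 0.46 with an estimated correlation), which with the endosperm markers stood highest in replicate 2 of 4 DAP. Root patterning genes (9 of 11 lower, 1 higher, median -1.03, adjusted p = 0.0091, and 0.46 with an estimated correlation) and HD-Zip IV genes (5 of 7 lower, 0 higher, median -0.80, adjusted p = 0.028, 0.46 with an estimated correlation and 0.051 without the libraries high in endosperm genes) fell. Histone genes (32 of 47 lower, 1 higher, and 32 and 3 adjusted over the list alone, median -0.59, adjusted p = 0.0022, and 0.51 with an estimated correlation) fell as well, the test of histone genes turning upward under normexp correction (adjusted p = 0.96). Ribosomal protein genes fell (170 of 288 lower, 17 higher, and 171 and 17 adjusted over the list alone, median -0.32, adjusted p = 0.0039, and 0.46 with an estimated correlation), but their median was 0.14 under normexp correction. Photosynthesis genes rose (9 of 26 higher, 3 lower, median 0.41, adjusted p = 0.0496, 0.48 with an estimated correlation and 0.051 without the libraries high in endosperm genes), but their median was -0.30 under normexp correction.

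The test called 9602 genes, 3716 higher and 5886 lower at 4 DAP, and 4109 of them changed at least 2-fold (1876 higher, 2233 lower). No slide held arrays of both stages. With the slide as a block, which ties 2 to 4 DAP through 3-DAP replicate 1 alone, 6614 genes passed and the medians were 3.81 for YABBY genes, 2.69 for oleosin and LEA genes and 4.20 for seed storage protein genes. They were -1.01 for root patterning genes (adjusted p = 0.096), -1.08 for HD-Zip IV genes, -0.53 for histone genes, -0.29 for ribosomal protein genes and 0.03 for photosynthesis genes (adjusted p = 0.46). With the unscaled deposited values 3357 genes were higher and 1603 lower, the median of all genes having moved by 0.39, and with normexp correction 2495 genes passed.

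**Figure D1:**
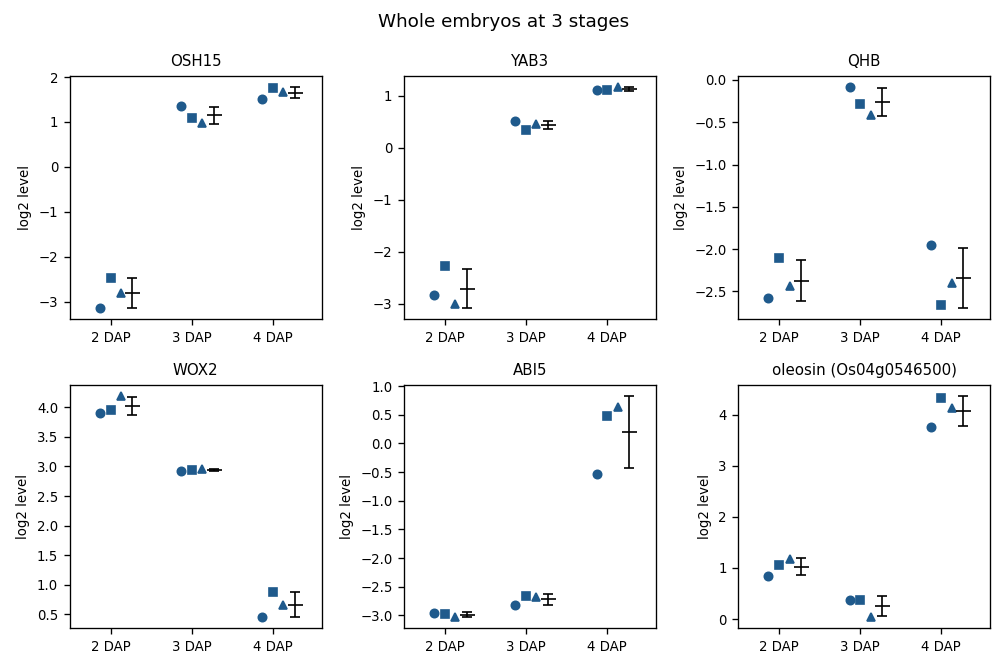
Log2 levels, relative to the 75th percentile of each array, of OSH15, YAB3, QHB, WOX2, ABI5 and the oleosin gene Os04g0546500 in whole embryos at 2, 3 and 4 DAP; circles, squares and triangles are replicates 1, 2 and 3, open where not well above background, and the dash with bars is the mean ± SD (n = 3). OSH15 and YAB3 rose by 3.96 and 3.14 from 2 to 3 DAP, QHB rose by 2.12 and then fell by 2.08, and ABI5 and the oleosin gene rose by 2.91 and 3.81 from 3 to 4 DAP.

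The comparison of the apical with the basal part of 3-DAP embryos asks which genes differ along this axis before organs form. Of the 4 YABBY genes tested 3 were higher in the apical part and 0 lower (median 6.01, too few for a list test). YAB5 was higher by 6.67 ± 0.70, YAB4 by 6.31 ± 0.76 with 2 of 3 basal arrays well above background, and YAB3 by 5.72 ± 0.42 with 1 of 3. All 4 HD-Zip III genes tested, transcription factor genes of apical identity and of the upper leaf side, were higher in the apical part (median 1.06), OSHB4 (Os03g0640800) by 2.74 ± 0.17 and OSHB1 (Os03g0109400) by 1.21 ± 0.12. PIN2 (Os06g0660200), for an auxin efflux carrier, was higher by 4.47 ± 0.33 in an auxin transport list with 3 of 5 higher and 1 lower (median 2.36, adjusted p = 0.0096, and 0.58 with an estimated correlation).

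WOX genes were lower in the apical part as a list, 4 of 6 lower and 1 higher (median -2.42, or -1.82 with bounds, adjusted p = 8.5e-05, and 0.34 with an estimated correlation). WOX12 (Os05g0564500) was at least 22.0-fold lower and DWT1 (Os01g0667400), a gene needed for tiller growth, at least 6.0-fold lower. QHB differed by -3.78 ± 0.30 with 2 of 3 apical arrays well above background, while WOX11 was at least 7.9-fold higher. WOX12 and DWT1 carry no description of function in the files. The AP2 gene PLT2 (Os06g0657500), of the PLETHORA group of root stem cell regulators, differed by -3.98 ± 0.28, and CRL5 (Os07g0124700), an AP2 gene of crown root initiation, by 3.53 ± 0.46. Root patterning genes as a list (3 of 11 higher, 4 lower, and 3 and 5 adjusted over the list alone, median -0.15) did not pass (adjusted p = 0.15), but did with the replicate block (adjusted p = 0.027) and with the slide as a block, which rests on apical replicate 3 (median -0.69, adjusted p = 0.00013). OSH1 (Os03g0727000), the KNOX gene of the shoot meristem, differed by -3.47 ± 0.33. The KNOX and shoot meristem genes as a list (3 of 10 higher, 5 lower, median -0.39) were past the threshold with the slide as a block (adjusted p = 0.0017) and not without it (0.15).

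The gene for the alpha-amylase/subtilisin inhibitor RASI (Os04g0526600) differed by -6.82 ± 1.11, and a Bowman-Birk trypsin inhibitor gene (Os01g0124200) differed by -6.04 ± 0.45. Peroxidase 1 (Os07g0639000), for a cell wall and stress enzyme, was at least 31.4-fold lower and the lipid transfer protein gene Os01g0691100 at least 51.4-fold lower. The lipid transfer protein list went the other way, 11 of 21 higher and 2 lower (median 1.01, adjusted p = 0.016, and 0.34 with an estimated correlation). So did ribosomal protein genes, 243 of 289 higher and 2 lower (252 and 2 adjusted over the list alone, median 0.63, adjusted p = 2.9e-24, and 0.34 with an estimated correlation). Oleosin and LEA genes were lower in the apical part (9 of 18 lower, 1 higher, median -1.33, or -1.32 with bounds, adjusted p = 0.00051, and 0.081 with an estimated correlation). HD-Zip IV genes were lower too (4 of 7 lower, 0 higher, median -0.37, adjusted p = 0.023, and 0.27 with an estimated correlation), with ROC6 (Os09g0526200) at -1.75 ± 0.23.

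In replicate 3 the median endosperm marker was above the mean of replicates 1 and 2 by 2.86 in the apical and 2.83 in the basal part. This was 1.28 in the ventral (0.35 over replicate 2 alone) and 0.83 in the dorsal part. Between the apical and the basal part 0 of 12 markers passed limma's test (0 at an unadjusted p under 0.05, list median -0.59, adjusted p = 0.53).

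The test called 6422 genes, 3776 higher and 2646 lower in the apical part, and 2140 of them changed at least 2-fold (844 higher, 1296 lower). With the slide as a block 3413 genes passed (1613 higher, 1800 lower). Within the shared slide, which held apical replicate 3 and all basal arrays, 588 passed (162 higher, 426 lower), so that the excess of higher genes depends on the setting. Both gave medians of -2.98 for WOX genes, 1.79 for auxin transport genes (adjusted p = 0.068 within the slide), 0.38 for ribosomal protein genes, -0.71 for oleosin and LEA genes, -0.52 for HD-Zip IV genes (0.10 within the slide) and 0.80 for lipid transfer protein genes (0.22 within the slide). Photosynthesis genes had a median of 1.85 (adjusted p = 0.00052 with the slide as a block), and stood at 0.02 without the block. With the unscaled deposited values 772 genes were higher and 1602 lower, with the median of all genes moved by -0.20.

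The comparison of the dorsal with the ventral part of 3-DAP embryos separates the side of the future scutellum from the side on which shoot and radicle form. OSH1 and HD-Zip III genes were higher in the ventral part, and lipid transfer protein and peroxidase genes in the dorsal part. OSH1 differed by -2.35 ± 0.33 in dorsal minus ventral (adjusted p = 0.0049), and all 4 HD-Zip III genes tested were lower in the dorsal part (median -1.54), OSHB4 at -2.38 ± 0.17, OSHB3 (Os12g0612700) at -1.81 ± 0.17 and OSHB2 (Os10g0480200) at -1.27 ± 0.11. A response regulator gene of cytokinin signalling (Os04g0673300) differed by -3.41 ± 0.24.

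The KNOX and shoot meristem genes were lower in the dorsal part as a list, with 2 of 10 lower and 0 higher (7 and 0 adjusted over the list alone, median -1.03, or -0.82 with bounds, adjusted p = 4.3e-08, and 0.084 with an estimated correlation). Lipid transfer protein genes were higher, 9 of 21 against 0 lower (10 and 0 adjusted over the list alone, median 0.89, adjusted p = 6.9e-23, and 0.014 with an estimated correlation), such as Os12g0115000 by 2.32 ± 0.21 and Os11g0116000 by 2.23 ± 0.23. Peroxidase genes shifted the same way (2 of 38 higher, 0 lower, and 4 and 1 adjusted over the list alone, median 0.28, or 0.26 with bounds, adjusted p = 0.0024, and 0.041 with an estimated correlation).

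Some lists shifted in small steps, with few or no members past the test on their own. Histone genes were lower in the dorsal part (1 of 47 lower, and 6 adjusted over the list alone, median -0.24, adjusted p = 1.7e-11, and 0.28 with an estimated correlation). Ribosomal protein genes shifted upward (median 0.14, adjusted p = 8.4e-10, and 0.71 with an estimated correlation), with 0 of 289 past limma's test and 28 at an unadjusted p under 0.05. Gibberellin metabolism genes shifted upward (0 of 6 past limma's test, 3 at an unadjusted p under 0.05, 3 higher and 0 lower adjusted over the list alone, median 0.44, adjusted p = 0.025, and 0.20 with an estimated correlation). This call ended with the slide as a block (median 0.40, adjusted p = 0.078) and with normexp correction (0.15). Cyclin genes shifted downward (0 of 12 past limma's test, 2 at an unadjusted p under 0.05, median -0.14, adjusted p = 0.046, and 0.32 with an estimated correlation). Their call ended with the replicate block (adjusted p = 0.084) and with normexp correction (0.11). Endosperm markers did not pass (median -0.08, adjusted p = 0.97) except with the slide as a block (median 1.31, adjusted p = 0.00053). That call rests on ventral replicate 1 as the only ventral array, in which Wx stood at -6.90 against 2.59 and 2.50 in replicates 2 and 3.

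The test called 276 genes, 171 of them lower and the others higher in the dorsal part, and 192 of them changed at least 2-fold. It called 415 with the replicate block, 135 with the slide as a block and 520 within the shared slide (267 higher, 253 lower), which held ventral replicate 1 and all dorsal arrays. The last 2 gave medians of -1.12 for KNOX and shoot meristem genes, 1.14 for lipid transfer protein genes, 0.16 for peroxidase genes, -0.24 for histone genes, -0.17 for cyclin genes and 0.08 for ribosomal protein genes. Without 1 of the 6 arrays it called 125 to 179. Without replicate 3 of the apical, basal and ventral parts it called 1303, and with the unscaled deposited values 32 higher and 87 lower.

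Across the 17431 genes, which are not independent replicates, the apical minus basal and the dorsal minus ventral changes had a Pearson correlation of -0.11 and a Spearman correlation of 0.051. The Pearson correlation was -0.14, -0.077 and -0.11 in replicates 1, 2 and 3 taken alone (SD 0.029), and 0.12 with the slide as a block. OSH1 was lower in both contrasts, while HD-Zip III genes were higher in the apical part and lower in the dorsal part.

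**Figure D2:**
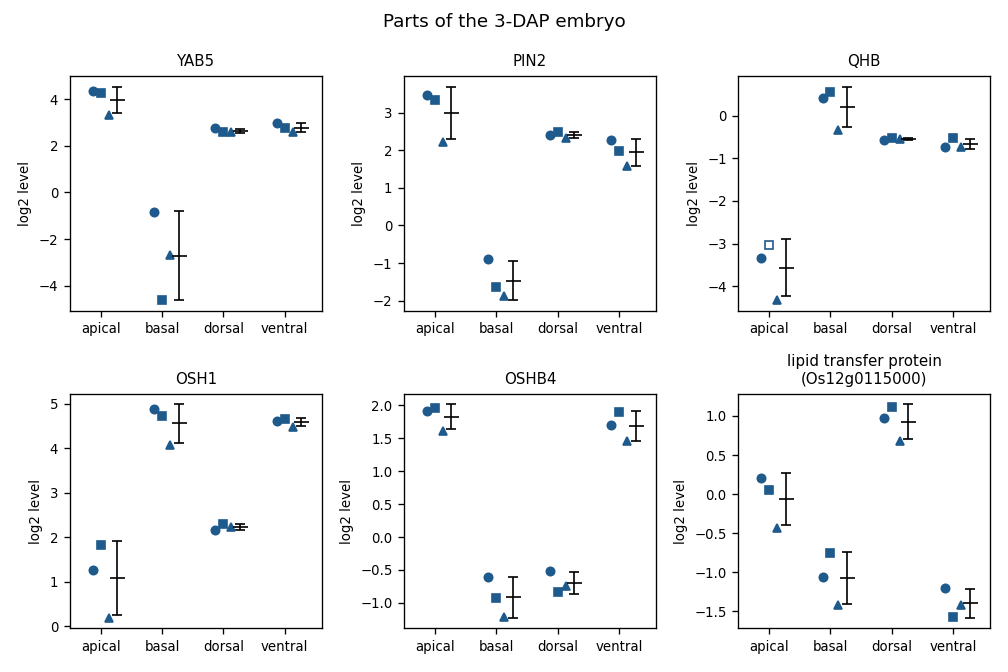
Log2 levels, relative to the 75th percentile of each array, of YAB5, PIN2, QHB, OSH1, OSHB4 and the lipid transfer protein gene Os12g0115000 in the apical, basal, dorsal and ventral parts of 3-DAP embryos; circles, squares and triangles are replicates 1, 2 and 3, open where not well above background, and the dash with bars is the mean ± SD (n = 3). YAB5 and PIN2 were higher in the apical than in the basal part by 6.67 and 4.47, and OSH1 and OSHB4 differed by -2.35 and -2.38 between the dorsal and the ventral part.

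**Figure D3:**
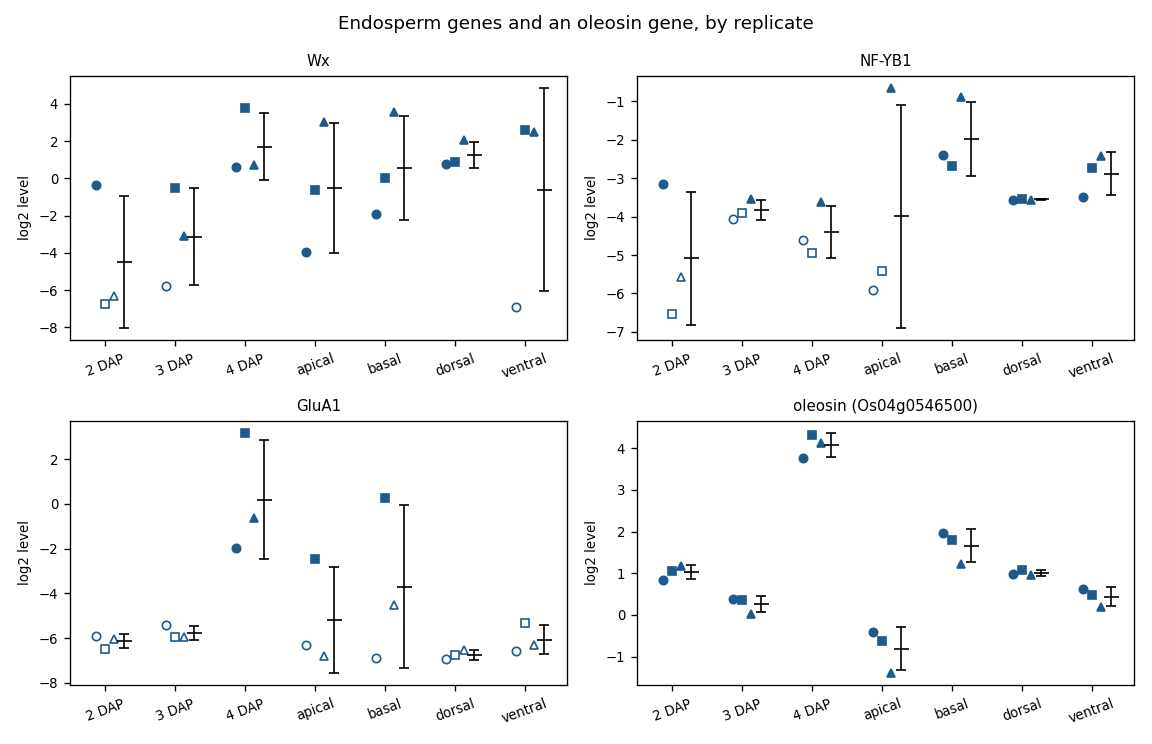
Log2 levels, relative to the 75th percentile of each array, of the starch synthase gene Wx, the endosperm transcription factor gene NF-YB1, the glutelin gene GluA1 and the oleosin gene Os04g0546500 in whole embryos and in parts of 3-DAP embryos; symbols and bars are as defined for the other plots of levels (mean ± SD, n = 3). GluA1 was highest in replicate 2 of 4 DAP, where the median endosperm marker stood 3.08 above its 3-DAP mean.

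Each 7-DAP organ was compared with the mean of the 3 others, so 1 outlying organ moves all 4 contrasts. YABBY genes were higher in the shoot, 6 of 7 against 0 lower (median 4.55, or 4.44 with bounds, adjusted p = 2.2e-14, and 0.062 with an estimated correlation), YAB5 at least 124.2-fold and YAB4 at least 94.3-fold. BOP1 (Os01g0948900), of a family that controls leaf base identity, was at least 8.9-fold higher. SHL4 (Os03g0449200), an ARGONAUTE gene needed to form the shoot in rice embryos, was at least 4.9-fold higher, and CRL5 at least 62.6-fold. All 4 HD-Zip III genes tested were higher (median 1.36), OSHB4 by 1.84 ± 0.17. SHR1 (Os07g0586900), for a mobile GRAS factor of tissue layering, was at least 9.5-fold higher, and GA2ox1 (Os05g0158600), for an enzyme that inactivates gibberellin, at least 16.3-fold.

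The KNOX and shoot meristem genes were higher in the shoot as a list (6 of 10 higher, 2 lower, and 7 and 2 adjusted over the list alone, median 0.81, adjusted p = 0.026, and 0.20 with an estimated correlation), though not with normexp correction (adjusted p = 0.12). OSH15 was higher by 1.59 ± 0.28 and OSH1 by 1.13 ± 0.21. Of 7 HD-Zip IV genes 3 were higher and 2 lower (median 0.37, adjusted p = 0.026, and 0.30 with an estimated correlation), a call that ended with the replicate block (adjusted p = 0.066). ROC1 (Os08g0187500) was higher by 2.75 ± 0.26 and ROC3 (Os10g0575600) by 2.10 ± 0.10. Of 13 auxin response factor genes, for transcription factors that carry the auxin signal, 8 were higher and 1 lower (median 0.35, adjusted p = 0.026, and 0.30 with an estimated correlation). The AP2 gene BBM1 (Os11g0295900), of the BABY BOOM group, differed by -5.03 ± 0.19 and PIN2 by -4.97 ± 0.36, each with 2 of 3 shoot arrays well above background. Root patterning genes had 3 of 11 higher and 6 lower in the shoot (median -0.66, or 0.00 with bounds, adjusted p = 0.0047, and 0.30 with an estimated correlation).

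Histone genes were higher in the shoot (31 of 46 against 0 lower, and 36 and 0 adjusted over the list alone, median 0.66, adjusted p = 7.8e-09, and 0.20 with an estimated correlation), with the H4 gene Os02g0684500 at 1.35 ± 0.19. DNA replication genes moved with them (12 of 22 higher, 1 lower, and 14 and 1 adjusted over the list alone, median 0.72, adjusted p = 0.0028, and 0.25 with an estimated correlation). So did ribosomal protein genes (172 of 289 higher, 2 lower, and 191 and 3 adjusted over the list alone, median 0.38, or 0.37 with bounds, adjusted p = 2.6e-11, and 0.30 with an estimated correlation). Alpha-amylase genes were lower in the shoot (3 of 6 lower, 0 higher, and 5 and 0 adjusted over the list alone, median -1.80, or -0.79 with bounds, adjusted p = 0.015, and 0.13 with an estimated correlation). Sugar transporter genes were lower (10 of 26 lower, 2 higher, and 11 and 3 adjusted over the list alone, median -0.45, or -0.25 with bounds, adjusted p = 0.026, and 0.13 with an estimated correlation). Peroxidase genes were lower as well (23 of 64 lower, 10 higher, and 24 and 12 adjusted over the list alone, median -0.41, or 0.00 with bounds, adjusted p = 0.032, and 0.20 with an estimated correlation), but did not pass with the replicate block (adjusted p = 0.097), with the slide as a block (0.056) or with normexp correction (0.16).

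The test called 6045 of 20354 genes, 3283 higher and 2762 lower in the shoot, 2571 of them by at least 2-fold (1272 higher, 1299 lower). From each of the 3 other organs 908 genes differed the same way (435 higher, 473 lower). No slide held all 4 organs. A slide block left 4416 genes and gave medians of 5.05 for YABBY genes, 0.80 for KNOX and shoot meristem genes, 0.42 for HD-Zip IV genes, -0.63 for root patterning genes and 0.69 for histone genes. The same block gave 0.80 for DNA replication genes, 0.51 for ribosomal protein genes, 0.27 for auxin response factor genes, -1.25 for alpha-amylase genes, -0.42 for sugar transporter genes and -0.29 for peroxidase genes. Between arrays of 1 slide, the median of YABBY genes was 4.25 in shoot minus epiblast. In shoot minus scutellum, with shoot replicate 1 as the only shoot array, it was 0.92, and that of alpha-amylase genes -5.53. Endosperm markers (median -2.21) and seed storage protein genes (-2.25) were also lower in this 1 library, in which GluA1 stood at 4.92 against 6.79 and 7.67 in shoot replicates 2 and 3, while over all arrays of the 2 organs they did not pass (medians -0.71 and -0.49, adjusted p = 0.25 and 0.12). Unscaled deposited values gave 1057 higher and 1475 lower, with the median of all genes moved by -0.12.

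The root had high levels of root patterning genes, auxin carriers and OSH1, and low levels of YABBY and lipid transfer protein genes. Of 11 root patterning genes 10 were higher and 0 lower (median 2.53, or 2.23 with bounds, adjusted p = 8.5e-20, and 0.012 with an estimated correlation). BBM2 (Os02g0614300) was at least 200.6-fold higher and BBM3 at least 27.8-fold. BBM4 (Os04g0504500), which carries no description in the files, was at least 16.5-fold higher, and QHB at least 9.5-fold. Of the 5 auxin transport genes 4 were higher and 0 lower (median 1.89, adjusted p = 7.3e-05, and 0.070 with an estimated correlation), PIN1a by 4.32 ± 0.41 and PIN1b (Os02g0743400) by 2.76 ± 0.14. Auxin response genes as a list (15 higher and 8 lower, median 0.22) passed with the replicate block (adjusted p = 0.023) and with the slide as a block (0.031), and not without them (0.053).

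OSH1 was higher in the root by 2.51 ± 0.21 and OSH71 by 2.11 ± 0.19. Their list of KNOX and shoot meristem genes had 5 of 10 higher and 1 lower (median 0.60, or 0.36 with bounds, adjusted p = 0.014, and 0.13 with an estimated correlation). Against the epiblast alone the list did not pass (median 0.49, adjusted p = 0.11). All 4 HD-Zip III genes tested were higher too (median 1.02), OSHB4 by 2.23 ± 0.17. All 7 YABBY genes were lower in the root (median -4.80, or -2.25 with bounds, adjusted p = 1.6e-12, and 0.012 with an estimated correlation), YAB3 at least 31.5-fold. Of 27 lipid transfer protein genes 20 were lower and 2 higher (21 and 3 adjusted over the list alone, median -2.94, adjusted p = 8.8e-31, and 0.010 with an estimated correlation), Os01g0822900 by a difference of -8.63 ± 0.70. HD-Zip IV genes were lower (3 of 7 lower, 1 higher, and 4 and 1 adjusted over the list alone, median -0.42, adjusted p = 2.0e-10, and 0.12 with an estimated correlation). They included ROC1 at -6.10 ± 0.26 and ROC2 (Os04g0627000) at -8.19 ± 0.36, the latter with 2 of 3 root arrays well above background.

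Photosynthesis genes were lower in the root (13 of 33 against 0 higher, and 14 and 0 adjusted over the list alone, median -0.78, adjusted p = 0.00027, and 0.24 with an estimated correlation). DNA replication genes were higher (13 of 22 higher, 0 lower, and 15 and 0 adjusted over the list alone, median 0.56, adjusted p = 0.0030, and 0.24 with an estimated correlation). Ribosomal protein genes were higher (152 of 289 higher, 24 lower, and 171 and 26 adjusted over the list alone, median 0.35, adjusted p = 9.9e-07, and 0.41 with an estimated correlation). Neither list passed with the slide as a block (adjusted p = 0.086 and 0.62). Endosperm markers did not pass in the root (median -0.94, adjusted p = 0.085), but did against the epiblast alone (-1.63, adjusted p = 0.020). The slide block, which rests on epiblast replicate 3 alone, gave -2.36.

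The test called 7383 genes, 4249 higher and 3134 lower in the root, 2915 of them by at least 2-fold (1337 higher, 1578 lower). From each other organ 1345 differed the same way (658 higher, 687 lower). A slide block left 1798 genes, with 7196 of the 7383 keeping their direction. The block gave medians of 2.32 for root patterning genes, 1.58 for auxin transport genes, 0.58 for KNOX and shoot meristem genes and -4.69 for YABBY genes. It gave -2.64 for lipid transfer protein genes, -0.77 for HD-Zip IV genes, -1.11 for photosynthesis genes, 0.34 for DNA replication genes and 0.07 for ribosomal protein genes. Between the 3 root arrays and epiblast replicate 3, the only other array of their slide, the medians were 3.42 for root patterning genes, -2.36 for YABBY genes and -3.35 for lipid transfer protein genes. Unscaled deposited values gave 6015 higher and 1054 lower, with the median of all genes moved by 0.51, and normexp correction 3498 higher and 3884 lower, with a shift of -0.13.

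The scutellum had high levels of lipid transfer protein genes and of 5 alpha-amylase genes and low levels of OSH1. Of 6 alpha-amylase genes 5 were higher and 0 lower (median 4.68, or 4.00 with bounds, adjusted p = 1.9e-05, and 0.053 with an estimated correlation). The isozyme 3E gene was higher by 10.61 ± 1.13 with 6 of 9 arrays of the other organs well above background, and the 3B gene (Os09g0457600) at least 91.3-fold. A sucrose transporter gene (Os03g0170900) was higher by 6.89 ± 0.59 and a MtN3-type sugar carrier gene (Os02g0301100) by 5.31 ± 0.29, but sugar transporter genes as a list did not pass (6 of 26 higher, 2 lower, median 0.10, adjusted p = 0.15). Lipid transfer protein genes were higher (18 of 27 against 2 lower, median 1.37, adjusted p = 1.3e-12, and 0.047 with an estimated correlation), Os08g0131200 by 10.41 ± 0.69 with 6 of 9 arrays of the other organs well above background. Photosynthesis genes were higher (8 of 33 against 2 lower, median 0.56, adjusted p = 0.0082, and 0.42 with an estimated correlation).

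YABBY genes were higher in the scutellum (5 of 7 against 1 lower, and 5 and 2 adjusted over the list alone, median 2.04, adjusted p = 0.020, and 0.25 with an estimated correlation), YAB3 at least 7.1-fold, though not with normexp correction (adjusted p = 0.085). HD-Zip IV genes were higher (4 of 7 against 1 lower, median 0.49, adjusted p = 0.031, and 0.17 with an estimated correlation), ROC2 by 3.53 ± 0.36. WOX6 was higher by 3.75 ± 0.48, and LEC1A (Os02g0725700), for a CCAAT-binding regulator of embryo development, by 2.83 ± 0.53. OSH1 differed by -5.64 ± 0.21 and OSH71 by -2.62 ± 0.19. Since OSH1 was so low in the scutellum, it lay above the mean of the other organs in shoot, root and epiblast alike. The KNOX and shoot meristem list had 6 of 10 lower and 1 higher (median -1.39, or -0.28 with bounds, adjusted p = 1.9e-06, and 0.12 with an estimated correlation). SHL4 was at least 4.8-fold lower and BBM2 at least 8.3-fold lower. Root patterning genes were lower as a list (9 of 11 against 2 higher, median -2.15, or 0.00 with bounds, adjusted p = 0.00031, and 0.13 with an estimated correlation). Of the 4 HD-Zip III genes 3 were lower (median -0.66).

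Ribosomal protein genes were lower in the scutellum (181 of 289 lower, 8 higher, and 190 and 9 adjusted over the list alone, median -0.42, or -0.41 with bounds, adjusted p = 6.9e-11, and 0.39 with an estimated correlation), and so were histone genes (19 of 46 lower, 0 higher, and 23 and 1 adjusted over the list alone, median -0.42, or -0.41 with bounds, adjusted p = 0.0015, and 0.39 with an estimated correlation). DNA replication genes moved with them (9 of 22 lower, 1 higher, and 10 and 1 adjusted over the list alone, median -0.43, adjusted p = 0.035, and 0.41 with an estimated correlation), while cyclin genes did not pass (8 of 15 lower, 2 higher, adjusted p = 0.15). Endosperm markers and seed storage protein genes did not pass (medians 0.41 and 0.38, adjusted p = 0.44 and 0.24). A slide block, resting on shoot replicate 1 as the only tie to other organs, gave 2.53 and 2.36. GluA1 was lowest there of all organ arrays, but at 4.92 above every array of younger embryos.

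The test called 7158 genes, 3205 higher and 3953 lower in the scutellum, 2927 of them by at least 2-fold (1481 higher, 1446 lower). From each other organ 1406 differed the same way (805 higher, 601 lower). A slide block left 1897 genes (1002 higher, 895 lower), with 7064 of the 7158 keeping their direction. Its medians were 6.16 for alpha-amylase genes, 2.02 for lipid transfer protein genes, 0.75 for photosynthesis genes, 2.41 for YABBY genes, and 0.89 for HD-Zip IV genes. They were -1.18 for KNOX and shoot meristem genes, -1.55 for root patterning genes, -0.25 for ribosomal protein genes, -0.52 for histone genes and -0.24 for DNA replication genes (adjusted p = 0.051). Shoot replicate 1 minus the 3 scutellum arrays of its slide had medians of 1.39 for KNOX and shoot meristem genes and -1.24 for lipid transfer protein genes. Unscaled deposited values gave 1172 higher and 2284 lower, with the median of all genes moved by -0.22.

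The epiblast sample had high levels of lipid transfer protein genes and of 2 WOX genes. Lipid transfer protein genes were higher (18 of 27 against 0 lower, and 21 and 0 adjusted over the list alone, median 1.44, adjusted p = 1.2e-08, and 0.030 with an estimated correlation), Os11g0620300 by 5.33 ± 0.93. WOX12 was at least 24.0-fold and DWT1 at least 5.5-fold higher. The WOX list had 3 of 7 higher and 1 lower (median 0.23, mean 1.48, adjusted p = 0.00065, and 0.17 with an estimated correlation). RASI was higher by 5.46 ± 0.67 and OSH1 by 2.00 ± 0.21. A MtN3-type sugar carrier gene (Os08g0535200) was higher by 7.03 ± 0.58 and a sucrose transporter gene (Os02g0576600) by 4.84 ± 0.40. The sugar transporter list had 8 of 26 higher and 2 lower (median 0.23, or 0.14 with bounds, adjusted p = 0.016, and 0.15 with an estimated correlation).

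Auxin transport genes were lower in the epiblast (4 of 5 against 0 higher, median -2.37, adjusted p = 0.00012, and 0.15 with an estimated correlation). PIN1b differed by -2.37 ± 0.14 and the AUX1-like influx carrier gene Os03g0244600 by -4.88 ± 0.21. All 4 HD-Zip III genes were lower (median -1.52), OSHB4 at -4.17 ± 0.17, and SHR1 was at least 15.7-fold lower. Root patterning genes (7 of 11 lower, 3 higher, median -1.35, or 0.00 with bounds, adjusted p = 0.012, and 0.34 with an estimated correlation) were lower except with the slide as a block (adjusted p = 0.23). YABBY genes were lower (3 of 7 lower, 0 higher, and 4 and 0 adjusted over the list alone, median -1.08, or 0.00 with bounds, adjusted p = 0.016, and 0.17 with an estimated correlation). Auxin response factor genes had 5 of 13 lower and 0 higher (6 and 2 adjusted over the list alone, median -0.32, adjusted p = 0.0020, and 0.34 with an estimated correlation).

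Among the lists lower in the epiblast were histone genes (27 of 46 lower, 2 higher, and 31 and 3 adjusted over the list alone, median -0.51, adjusted p = 0.00016, and 0.34 with an estimated correlation) and DNA replication genes (14 of 22 lower, 0 higher, and 16 and 0 adjusted over the list alone, median -0.79, adjusted p = 4.6e-05, and 0.17 with an estimated correlation). Ribosomal protein genes were lower (129 of 289 lower, 3 higher, and 150 and 7 adjusted over the list alone, median -0.30, adjusted p = 1.1e-06, and 0.48 with an estimated correlation). Cyclin genes (7 of 15 lower, 1 higher, and 8 and 1 adjusted over the list alone, median -0.38, or -0.28 with bounds, adjusted p = 0.036, and 0.17 with an estimated correlation) did not pass with the slide as a block (0.077) or normexp correction (0.078). Endosperm markers (0 of 16 past limma's test, 9 at an unadjusted p under 0.05, median 1.13, adjusted p = 0.028, and 0.57 with an estimated correlation) were higher. Seed storage protein genes (2 of 35 higher, 1 lower, median 0.99, adjusted p = 0.023, and 0.57 with an estimated correlation) were higher with them. Under the slide block their medians were 0.30 and -0.13 (adjusted p = 0.55 and 0.71).

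The test called 6584 genes, 2833 higher and 3751 lower in the epiblast, 2496 of them by at least 2-fold (1381 higher, 1115 lower), and 1078 differed the same way from each other organ. A slide block left 3632 genes and gave medians of 1.27 for lipid transfer protein genes, 0.09 for WOX genes, 0.21 for sugar transporter genes, -2.36 for auxin transport genes, -1.36 for YABBY genes and -1.32 for root patterning genes. It gave -0.39 for auxin response factor genes, -0.42 for histone genes, -0.64 for DNA replication genes, -0.40 for cyclin genes and -0.32 for ribosomal protein genes. Between shoot and epiblast arrays of 1 slide the median of lipid transfer protein genes was -1.17 and that of endosperm markers -0.40 (adjusted p = 0.37). Unscaled deposited values gave 1017 higher and 1502 lower, with the median of all genes moved by -0.17.

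The 200 genes that differed most toward each 3-DAP part were then examined in the 7-DAP organs. Of the 200 genes, 95 of the dorsal and 29 of the ventral set had not passed the test between these parts. Genes of the basal part were higher in the epiblast (123 of 177 higher, 9 lower, median 1.23, adjusted p = 8.1e-37, and 0.00071 with an estimated correlation) and lower in the shoot (median -0.99, adjusted p = 1.7e-18, and 0.0022 with an estimated correlation). These medians were 0.71 and -0.62 with larger sets and 1.90 and -1.23 with 100 genes per set. They were 0.63 and -0.47 with sets chosen without replicate 3 of the apical, basal and ventral parts. Ventral replicate 2, as high in Wx, was kept. Genes of the ventral part were higher in the shoot (108 of 172 higher, 11 lower, median 1.18, adjusted p = 4.9e-29, and 0.0077 with an estimated correlation) and lower in the epiblast (median -1.06, adjusted p = 6.3e-22, and 0.021 with an estimated correlation). These medians were 0.71 and -0.56 with normexp correction and 0.60 and -0.45 with larger sets, and -0.61 in the epiblast with the slide as a block. Genes of the dorsal part were higher in the scutellum (19 of 193 lower, more higher, median 0.53, adjusted p = 2.1e-15, and 0.0050 with an estimated correlation). They were lower in the root (median -0.42, or -0.20 with larger sets and -0.71 with 100 genes per set, adjusted p = 1.2e-06, and 0.021 with an estimated correlation) and in the shoot (median -0.47, or -0.19 without replicate 3, -0.16 with the slide as a block and -0.24 with larger sets, adjusted p = 5.8e-06, and 0.030 with an estimated correlation).

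Genes of the apical part were higher in the shoot (96 of 196 higher, 29 lower, median 0.66, adjusted p = 1.4e-12, and 0.086 with an estimated correlation) and lower in the epiblast (median -0.70, adjusted p = 1.6e-23, and 0.057 with an estimated correlation). Without replicate 3 these medians were 0.54 and -0.50. In the scutellum apical genes were higher (101 higher, 34 lower, median 0.81, adjusted p = 1.0e-12, and 0.060 with an estimated correlation), but their median was 1.36 with 100 genes per set, 0.26 without replicate 3, 0.12 with normexp correction and 0.0064 with larger sets. Ventral genes were lower in the scutellum (median -0.57, or -0.32 with normexp correction and -0.35 with larger sets, adjusted p = 0.00011, and 0.17 with an estimated correlation). Basal genes were also lower there (median -0.34, or -0.088 without replicate 3, -0.11 with larger sets, -0.91 with 100 genes per set, -0.69 with the replicate block and -0.54 with the slide as a block, adjusted p = 0.00039, and 0.19 with an estimated correlation).

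In the root the sets of 3 parts depended on the setting. The test of apical genes pointed downward there (median -0.11, adjusted p = 1.7e-05, and 0.34 with an estimated correlation), but the median was -0.67 with 100 genes per set, -0.41 with the slide as a block and -0.27 with the replicate block, and 0.032 with quantile normalization, 0.043 without replicate 3 and 0.20 with larger sets, where the call was lost (adjusted p = 0.15). Ventral genes were higher in the root (median 0.40, or 0.19 with normexp correction, adjusted p = 0.018, and 0.34 with an estimated correlation), a call lost with the slide as a block (adjusted p = 0.065), with 100 genes per set (0.88) and with larger sets (0.12). Basal genes did not shift in the root (median -0.01, adjusted p = 0.99), but passed with the slide as a block (adjusted p = 0.017) and with normexp correction (0.022). Dorsal genes did not shift in the epiblast (median 0.17, adjusted p = 0.16), but passed with the replicate block (adjusted p = 0.0049), with 100 genes per set (0.0052) and on z-scores (0.023). Of the 16 tests 14 passed, 7 of them also with an estimated correlation.

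**Figure D4:**
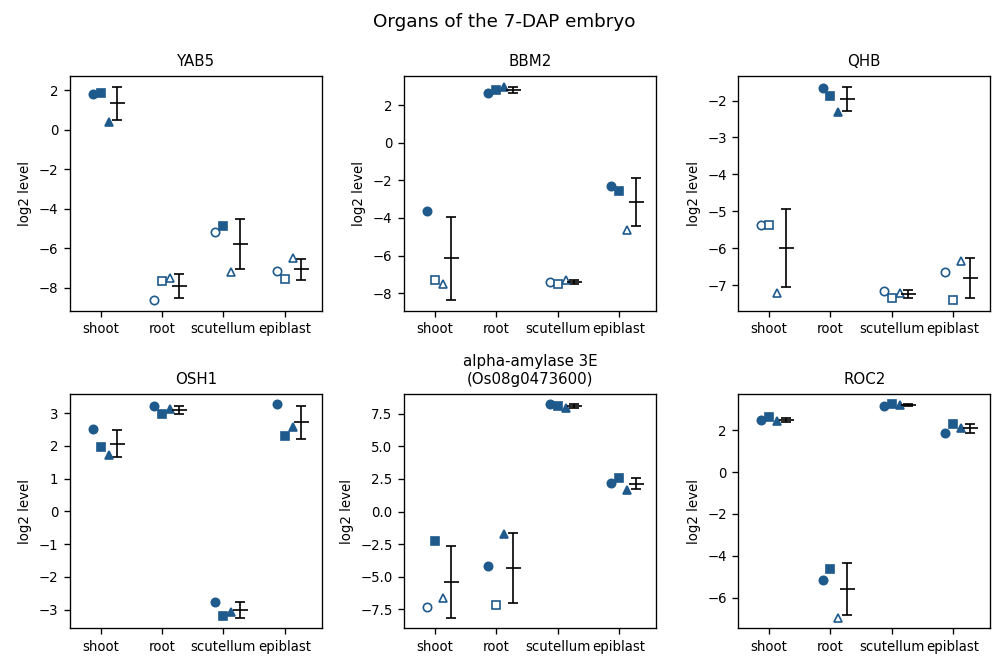
Log2 levels, relative to the 75th percentile of each array, of YAB5, BBM2, QHB, OSH1, the alpha-amylase isozyme 3E gene and ROC2 in the shoot, root, scutellum and epiblast of 7-DAP embryos; circles, squares and triangles are replicates 1, 2 and 3, open where not well above background, and the dash with bars is the mean ± SD (n = 3). OSH1 was higher in the root by 2.51 and differed by -5.64 in the scutellum, and the alpha-amylase 3E gene was higher in the scutellum by 10.61.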

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

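Except for the tests of endosperm RNA and of a later stage in the parts of 3-DAP embryos, the tests in this part were chosen after the results they bear on were seen. The array holds 588 probes without a gene locus, which entered no comparison, and 15 of them were well above background on all 33 arrays while 252 were on none. No biological explanation was tested for this signal.

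In replicate 3 of apical, basal and ventral parts, endosperm markers exceeded the mean of replicates 1 and 2 (medians 2.86, 2.83 and 1.28). The 1.28 rests on a low ventral replicate 1. In the mean of the 3, 11 of 12 were above 0 (median 2.29). If these libraries held endosperm RNA, other genes that follow the markers in whole embryos would be raised by over 1. The 100 such genes had a median of 0.463 (90 above 0, quartiles 0.125 and 2.12, 0.19 in dorsal replicate 3), between the 2 bounds, which leaves this open. The slide is argued against for basal replicate 3, which stood 2.83 above replicates 1 and 2 of its own slide, and stays open for ventral replicate 3, which differed by 0.35 from replicate 2 of its slide; a single test over both was first run and then split. Embryos of a later stage would lower genes that fall from 3 to 4 DAP. The 200 lowered most had a median of -0.293, near the bound of -0.3, so this stays open too. By part the median was -0.47, -0.40 and -0.10 (all genes -0.19, -0.09 and -0.04), and -0.12 in dorsal replicate 3. RNA from endosperm may be a source, and 7 storage genes (medians -0.32, 0.14 and 0.11) cannot tell, as 3-DAP endosperm was not measured.

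Seed storage protein genes were highest in replicate 2 of the 4-DAP whole embryos, where the 21 tested stood a median of 3.98 above replicates 1 and 3. Endosperm markers that are no storage protein genes were higher there by a median of 1.983, in 11 of 11 tested. This test replaced one of storage genes that had been seen. Endosperm RNA is a candidate for the excess, though the untested NF-YB1 was dim and lowest there (-4.94). Endosperm RNA was not tested for replicates 1 and 3, in which 19 of 21 were above 3 DAP (median 1.87). A biological difference between embryos of this age was not tested.

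Oleosin and LEA genes rose from 3 to 4 DAP as well. RNA from endosperm in 1 library is argued against as the cause, since the 15 members tested differed by a median of -0.079 between replicate 2 and replicates 1 and 3 (6 above 0, quartiles -0.44 and 0.23), and replicates 1 and 3 stood 2.39 above 3 DAP (13 of 15). A test of the members that rose (-0.28) was replaced by this one, since they were chosen by their rise. That the rise belongs to the embryo remains a hypothesis.

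Other splits of the samples were fitted for every comparison. The comparisons of whole embryos and parts called 4923, 8234, 9602, 6422 and 276 genes and their highest other splits 0. Only the real split was as large, and 10 splits are too few for a share under 0.05. For shoot, root, scutellum and epiblast only the real of 100 splits called as many genes. It called 6045, 7383, 7158 and 6584, and the highest others 1601, 4620, 3038 and 2706. For the organs this argues against random grouping, not against effects of slide or shared embryos.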

How the results depend on the processing

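Normexp followed by quantile normalization, the runs without arrays at 1 slide position, without 2 libraries high in endosperm genes or without replicate 3 of 3 parts, and z-scores and cleaned lists were chosen after seeing the data. The cause was not tested except where a setting's own construction shows it, as with a stricter threshold or fewer arrays.

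In 3 against 2 DAP, 4923 genes passed, and normexp gave 121, the deposited values 1500, array weights 7546, a run without the arrays at position 4 of a slide 3248 and a 2-fold threshold 1574. In 4 against 3 DAP, normexp gave 1321, the deposited values 3512 and the 2-fold threshold 2814 in place of 8234. In 4 against 2 DAP these gave 2495, 4960 and 4109 in place of 9602. Normexp followed by quantile normalization gave 4334 and 7339 in the first 2. The replicate block gave 4133, 7532 and 9017 in the 3 comparisons, where equal replicate numbers had correlations of deviations between -0.149 and 0.019, and runs without the libraries high in endosperm genes 3812, 7397 and 8161.

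For apical against basal, 6422 genes became 2374 with the deposited values, 9737 with array weights, 3413 with the slide as a block, 3480 with only the 2 groups in the fit, 588 within the shared slide and 2140 at 2-fold, and 9487 without replicate 3 of 3 parts. Without 1 array the count ran from 4802 to 8517. For dorsal against ventral, 276 became 135 with normexp, 119 with the deposited values, 181 with the strict filter, 2241 with array weights, 415 with the replicate block, 135 with the slide as a block, 932 with only the 2 groups, 520 within the shared slide and 1303 without replicate 3 of 3 parts. Without dorsal replicate 1, 2 or 3 it was 145, 129 and 139, and without a ventral one 179, 125 and 161.

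In the organs, 6045, 7383, 7158 and 6584 genes passed for shoot, root, scutellum and epiblast. The 2-fold threshold gave 2571, 2915, 2927 and 2496 and the demand on each of the 3 other organs 908, 1345, 1406 and 1078. The deposited values gave 2532, 3456 and 2519 for shoot, scutellum and epiblast, and the slide as a block 1798, 1897 and 3632 for root, scutellum and epiblast. Every probe as its own feature gave 9131 for the shoot. The replicate block gave 7874, 9191, 8762 and 8283.

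Of list tests 80 passed, 7 with an estimated correlation and 130 with fry. The other settings gave 78 to 89. Under normexp the test's direction turned for histone genes in 4 against 3 and 4 against 2 DAP (medians -0.12 and -0.18) and ribosomal protein genes in 4 against 2 DAP (0.14). Only the median turned for photosynthesis genes in 4 against 2 DAP (-0.30) and, with the slide as a block, for seed storage protein genes in the epiblast (-0.13). Without the libraries high in endosperm genes 4 list calls of whole embryos ended. Of all runs of lists that had passed, those with an estimated correlation included, 544 kept direction and threshold, 128 lost the threshold and 3 reversed. Of the 14 sets of regional genes that passed, 7 did with an estimated correlation, and of all runs, these included, 115 kept both and 11 lost the threshold.

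The correlation of the 2 axes, -0.108, was -0.0256 with normexp, -0.147 over called genes, and reversed to 0.118 with the slide as a block. Without 1 array it ran from -0.122 to -0.0640.

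Of runs of named genes that were called, 13366 kept direction and threshold, 901 lost the threshold and 7 reversed. These were, with normexp, Os08g0520500, 4 DAP vs 3 DAP (-0.18), Os01g0302500, 4 DAP vs 2 DAP (-0.42), Os07g0148900, 4 DAP vs 2 DAP (-0.0669), Os12g0577700, root vs other organs (-0.0938), Os05g0243200, root vs other organs (-0.0711) and Os11g0187600, root vs other organs (-0.0485), and with the slide as a block Os09g0457600, 4 DAP vs 2 DAP (-0.0446). In the 3 sets 12493, 12258 and 9335 loci were not kept, and of these 4008, 4200 and 3305 had another probe above background on an array.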

Other observations

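Some lists fixed in advance for embryo biology passed in no comparison in the main setting. Auxin response genes, which include the Aux/IAA repressors, passed in 0 of 9 list tests with cameraPR of limma (2 at an unadjusted p under 0.05, 7 with fry, lowest adjusted p = 0.053), with 15 of 39 higher and 8 lower in the root and 6 higher and 13 lower in the scutellum. In the scutellum they passed with the replicate block (adjusted p = 0.039). Expansin genes, for proteins that loosen cell walls, passed in 0 of 9 (3 at an unadjusted p under 0.05, 3 with fry, lowest adjusted p = 0.075). Embryo maturation regulators passed in 0 of 9 (1 at an unadjusted p under 0.05, 3 with fry, lowest adjusted p = 0.052, in the scutellum, where 3 of 5 were higher). Heat shock protein genes passed in 1 of 9, and auxin response factor, sugar transporter, cyclin, gibberellin metabolism and peroxidase genes in 2 of 9 each. Oleosin and LEA genes, which rose in whole embryos, did not pass in the 4 organs (lowest adjusted p = 0.055, in the shoot).

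Among single regulators of the seed, VP1 (Os01g0911700), the B3 regulator of seed maturation, was called in 0 of 9 comparisons by limma (1 at an unadjusted p under 0.05, the epiblast, -0.29 ± 0.11), with a difference of 0.21 ± 0.18 from 3 to 4 DAP. DL (Os03g0215200), a YABBY gene of leaf midribs and carpels, was higher in the scutellum by 0.99 ± 0.28 and differed by -0.80 ± 0.28 in the root, and neither call was kept with the slide as a block. GA3ox2 (Os01g0177400), for the last step of gibberellin synthesis, was well above background on no array of whole embryos and of the parts, and was not tested.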
